A study of Homo sapiens with 24 samples.

How the data were processed

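Gene expression was measured in 24 samples of HepaRG cells, 3 at each of 8 times after replating, on a 1-colour Affymetrix human expression array with 22283 probe sets, 68 of them controls. Per the labels' protocols, RNA was extracted with a column kit and biotin-labelled cRNA was prepared from 100 ng of total RNA with a 3' in vitro transcription kit, so the array reads mainly the 3' ends of transcripts. The deposited values are linear intensities, 1 signal per probe set and array. MAS5 made these intensity values, per the submitters' processing notes; its version and scaling target are not given in the sources used here. In the deposited table the mean signal of every array, without the lowest and highest 2% of probe sets, lay just under 500 (499.8 for 0 h replicate 1), so each array had been scaled to a common level. The table used here holds no detection calls, and scanner images were not used here.

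Samples were grouped by the time in their labels. The labels number the replicates 1 to 3 and do not say whether they came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. No 2 arrays held identical values. The number of arrays limits the precision.

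Signals of the 22215 probe sets that are not controls entered as log2(signal + 18), where 18 is the 20th percentile of all signals. No other normalization between arrays was added. A fold change is therefore on the log2(signal + 18) scale, which understates the change of dim genes. A probe set was tested if at least 3 of the 24 arrays lay above their own 40th percentile, which 17122 probe sets did. Gene symbols came from the array's annotation table. It gave 1 symbol for 19065 of the probe sets, several for 1043 and none for 2107, and no gene was named from a probe set with several symbols. Through gene identifiers, 19053 probe sets were looked up in a current table of names, which changed 0 symbols. Each gene was represented by its tested probe set with the highest mean, which left 9966 genes. For 763 of these the probe set has a name ending in _x_at, which marks possible cross-hybridization with similar transcripts, so a gene named from such a probe set is uncertain and is marked so in the text. No reference genome was used here, so no genomic positions are given.

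Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts of group means, eBayes with a mean-variance trend, 16 residual degrees of freedom before moderation) over all 24 arrays, without the replicate number as a block. A gene was called changed at an adjusted p under 0.05 (Benjamini-Hochberg over the 9966 genes of a comparison, two-sided) and a difference of at least 2-fold. The comparisons were the 7 later times with 0 h, the 6 steps between neighbouring times after 1 h, and 48 h with 1 h. A moderated F-test covered the 7 comparisons with 0 h together. Log2 changes are given with their standard error (SE). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

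Gene lists, 39 in all, were written before the data were examined, as were the comparisons, thresholds, named-gene rule and alternatives listed below. They covered liver functions, early response and inflammatory genes, signalling pathways, cell cycle, stress and metabolism, and markers of other cell types. Every list was tested in every comparison with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 39 lists of a comparison. Camera asks whether a list moved relative to all other genes. Beside it stood camera with the correlation estimated from the residuals, and fry, which asks whether the list's own genes move one way on balance. Members called were also counted with p-values adjusted over the list alone. Of the 39 lists, 30 were called in at least 1 comparison with 0 h. The numbers called at the 7 later times were, in order of time, 10, 22, 19, 23, 24, 23 and 21 with the preset correlation, and 9, 13, 16, 18, 19, 21 and 19 of these held with an estimated correlation. The lists share some members, so their counts are not independent.

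Genes were named by a fixed rule. For each later time against 0 h it took the 6 largest rises and the 6 largest falls among called genes whose 3 values all lay beyond all 3 values at 0 h. For each step it took 2 and 2 by the same criterion. From each list it took up to 3 called members with the largest change, in the comparison with 0 h that called most members. A further set of liver, inflammatory, junction, progenitor and cell cycle genes was named always where measured. TNF and EPCAM, which belonged to that set, did not pass the filter on low signals. Some genes that meet the rule are not described one by one. Genes outside it are marked in the text as chosen after their values were seen.

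Alternatives were no pseudocount, a larger pseudocount (73.8, the 40th percentile), quantile normalization, centring each array on its median, no filter, a stricter filter, the mean of a gene's probe sets, leaving out _x_at probe sets, no mean-variance trend, a fit with only the groups compared, the replicate number as a block, and leaving out each replicate in turn. For lists, leaving out each replicate was added after the data had been seen, because 0 h replicate 2 stood apart in RNA quality. The same steps were tested on simulated data for 48 h against 0 h, with 200 of 9966 genes changed by known amounts. Of 50 genes changed 1.5-fold, 1 was called, and of 50 each changed 2-, 3- and 4-fold, 15, 35 and 41 were called. Of 9766 unchanged genes, 2 were called. A gene not called is thus not shown to be unchanged. At 2-fold, 25 of 50 genes passed the adjusted p, so the 2-fold limit also cost calls. The real comparison of 48 h with 0 h called 2149 genes, so its adjusted p was less strict, and these rates need not hold there.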

Results

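HepaRG is a human liver progenitor cell line that forms hepatocyte-like and biliary-like cells when it is kept confluent and then exposed to DMSO. The cultures had grown for 2 weeks and had then been kept for 2 weeks with DMSO. The hepatocyte-like cells were lifted off with mild trypsin and replated sparsely, which per the labels served to induce reprogramming. RNA was collected at 8 times from 0 h to 48 h, and 3 arrays were made at each time. Each later time was compared with 0 h, and neighbouring times with each other, to describe how expression moved over this course.

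The median signal of an array was 135.2 ± 6.11 at 0 h and 109.9 ± 4.1 at 48 h (SD, n = 3). The 3'/5' signal ratio of the ACTB control probe sets, a measure of RNA integrity that is higher for degraded RNA, was 3.83 ± 2.7 at 0 h and 1.16 ± 0.13 at 48 h (SD, n = 3). It was 6.91 on 0 h replicate 2, against 2.03 and 2.56 on the other 0 h arrays. For both measures the exact permutation test between 0 h and 48 h gave p = 0.1 (two-sided), the smallest that 3 arrays against 3 can give. Counts without 0 h replicate 2 are therefore given beside several gene groups. Counts of other groups moved too: without it 11 of 24 NF-kappaB response genes rose at 1 h (9 with all arrays), 9 of 20 cytokines and chemokines at 4 h (7), and at 16 h 9 of 19 fatty acid oxidation genes (11) and 6 of 21 IL-6 and JAK-STAT genes (8) fell. The ACTB ratios of the other 0 h arrays also lay above those at 48 h, so leaving out 1 array does not remove a difference in RNA integrity between times. Such a difference was not tested as a cause of the changes. Across genes, arrays of one time correlated at 0.936 to 0.968 and arrays of different times at 0.838 to 0.959. The best-correlated partner was of the same time for 21 of 24 arrays. The first 2 principal components held 32.6% and 14.7% of the variance.

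Of 9966 genes, 5870 (58.9%) differed at some time by limma's moderated F-test, and 3549 of these also reached a 2-fold difference from 0 h. Compared with 0 h, 281 genes were changed at 1 h, 1466 at 4 h, 1846 at 8 h, 1921 at 12 h, 2104 at 16 h, 2158 at 24 h and 2149 at 48 h. The steps called 1089 genes from 1 to 4 h, 321 from 4 to 8 h, 48 from 8 to 12 h, 24 from 12 to 16 h, 131 from 16 to 24 h and 119 from 24 to 48 h. The median log2 change of all genes against 0 h was -0.086 at 1 h, -0.163 at 4 h, -0.147 at 8 h, -0.132 at 12 h, -0.156 at 16 h, -0.094 at 24 h and -0.118 at 48 h, and centring the arrays brought it to between -0.033 and 0.036. The balance of higher and lower calls therefore depended on scaling. At 1 h 78.6% of the called genes were higher (81.6% with quantile normalization, 85.5% with median centring). From 4 h on, in order of time, the share was 51.6%, 45.4%, 45.2%, 43.5%, 48.1% and 45.6%. It was 57.2%, 52.1%, 50.9%, 52.9%, 54.5% and 53.1% with quantile normalization and 64.6%, 59.2%, 57.3%, 61.1%, 58.8% and 57.8% with median centring, so falls outnumbered rises only under the scaling used.

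**Figure D1:**
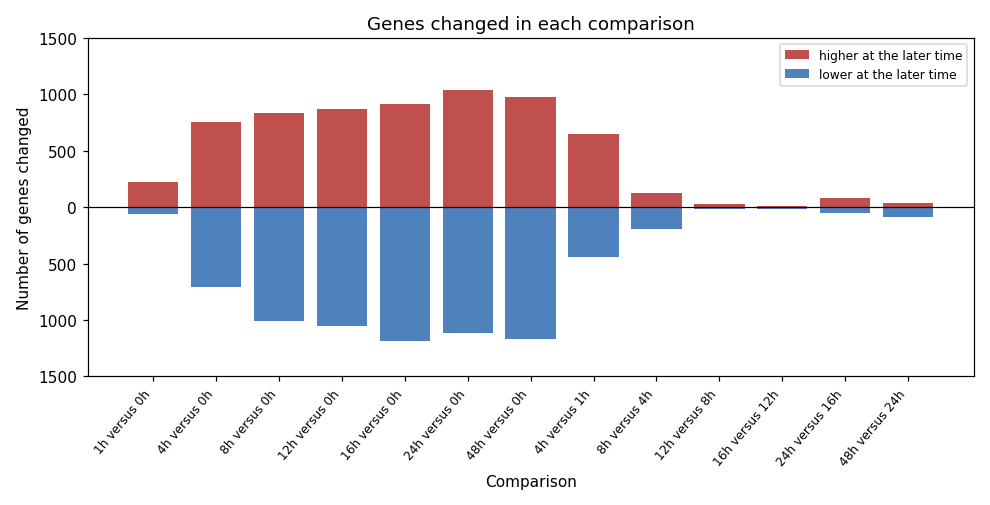
Bars give the number of genes called higher (upward) and lower (drawn downward) in each comparison, for the 7 later times against 0 h and for the 6 steps between neighbouring times. Calls against 0 h increased from 281 at 1 h to 2149 at 48 h, while the step from 12 to 16 h called 24 genes.

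In the first hour, transcripts of chemokines, immediate early genes and NF-kappaB response genes rose. CCL2, a chemokine that attracts monocytes, went from a signal of 60.7 ± 31.3 to 4040 ± 914 (SD, n = 3), a log2 change of 5.75 ± 0.21 (SE, adjusted p = 2.4e-19). MAFF, a small bZIP transcription factor, rose by 5.35 ± 0.30 (3.17 by its other probe set), GEM, a small GTP-binding protein, by 4.85 ± 0.25 and DUSP5, a phosphatase of ERK kinases, by 4.82 ± 0.34 on the log2 scale. The RAS-related gene RRAD rose by 4.71 ± 0.30 and FILIP1L by 4.62 ± 0.32. Of the 281 genes called at 1 h, 221 were higher and 60 lower than at 0 h.

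Of 42 measured immediate early genes, 22 rose at 1 h (23 adjusted over the list alone), with a list median of 1.10 and camera adjusted p = 3.7e-46. Without 0 h replicate 2, whose ACTB 3'/5' ratio was 6.91, 24 rose. IER3, an early gene linked to survival signalling, rose from 921 ± 378 to 11700 ± 884 (SD, n = 3). Of 20 cytokines and chemokines, 9 rose (10 adjusted over the list alone, camera adjusted p = 8.4e-23), among them CCL20, a chemokine for CCR6-bearing leukocytes, which went from 999 ± 785 to 20300 ± 2740 (SD, n = 3, adjusted p = 8.7e-14), and CXCL3, a neutrophil chemoattractant, with a log2 change of 4.42 ± 0.46. IL6, the cytokine that drives the hepatic acute phase response, rose from 86.6 ± 18.1 to 577 ± 48.4 (adjusted p = 5.9e-08). CXCL8, another neutrophil chemoattractant, rose by 3.04 ± 0.37, but its probe set is of the _x_at kind and uncertain. Its other probe set, not of that kind, gave 4.46, so the size of the rise is what stays uncertain. Of 24 NF-kappaB response genes, 9 rose (12 adjusted over the list alone, camera adjusted p = 8.4e-23). Other lists called higher at 1 h were clock genes with 4 of 14 members (4 adjusted over the list alone, camera adjusted p = 3.3e-07), TGF-beta response genes with 6 of 26 (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 9.9e-05), growth factors and receptors with 6 of 28 (6 adjusted over the list alone, camera adjusted p = 0.00019), glucocorticoid response genes with 3 of 18 (4 adjusted over the list alone, camera adjusted p = 0.00058) and cholangiocyte markers with 2 of 13 (3 adjusted over the list alone, camera adjusted p = 0.0011). Of 16 progenitor and stem cell genes, 5 rose (5 adjusted over the list alone, camera adjusted p = 0.0044), although the list median was -0.36 and its mean 0.47. Of 26 YAP and SRF targets, 4 rose and 3 fell, with camera adjusted p = 0.018 for a rise (4 and 3 adjusted over the list alone), and this call was lost with adjusted p = 0.10 with an estimated correlation.

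Among single genes followed throughout, SNAI2, a zinc-finger repressor active in epithelial-mesenchymal transition, rose at 1 h from 1220 ± 262 to 6300 ± 671 (SD, n = 3; adjusted p = 4.2e-12). SOX9, a transcription factor of bile duct and progenitor cells, rose by 2.31 ± 0.17 and the proto-oncogene MYC by 2.18 ± 0.21. FOS and EGR1, classical immediate early transcription factors, were already bright at 0 h, at 6620 ± 2600 and 8040 ± 3520 (SD, n = 3). Their log2 changes at 1 h of -0.76 ± 0.43 and -0.14 ± 0.21 were not called. Among the falls at 1 h were CAD, the enzyme that starts pyrimidine synthesis, with -2.14 ± 0.38, and METTL8 with -2.04 ± 0.37. The number of lower genes at 1 h was the least stable count of this comparison: it was 25 with the larger pseudocount, 39 with the stricter filter and 22 when only the groups compared entered the fit, against 60.

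**Figure D2:**
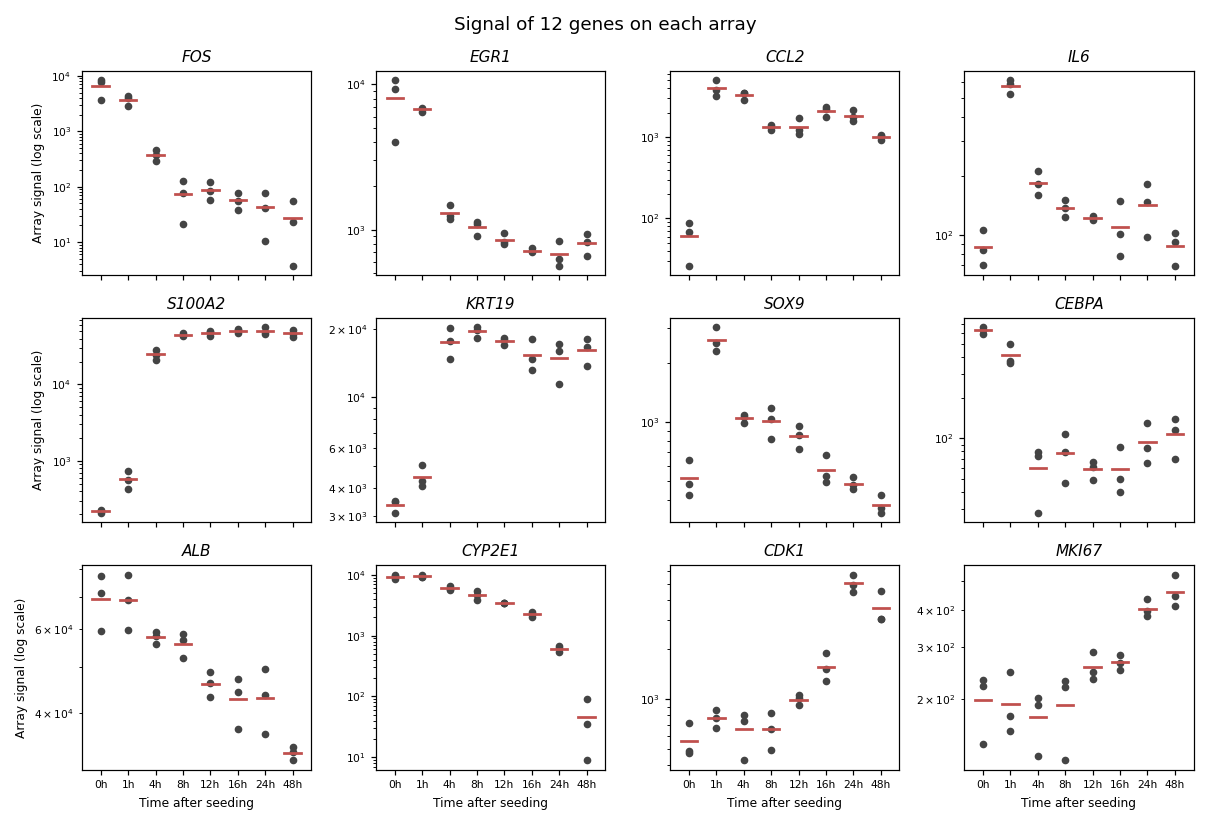
Each panel plots 1 of 12 genes, with array signal on a log axis against time in hours. Points are single arrays, and each short red line marks the mean of 3 arrays. CCL2 was highest at 1 h with a mean of 4040, FOS and EGR1 were highest at 0 h, and S100A2, KRT19 and CDK1 were higher at 48 h than at 0 h, while CEBPA, ALB and CYP2E1 were lower.

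Between 1 and 4 h, cytoskeletal, ribosome biogenesis and metallothionein genes rose and many early genes fell. In the step from 1 to 4 h, 646 genes were higher and 443 lower. FOSB, an immediate early transcription factor, fell in this step from 4850 ± 498 to 334 ± 127 (SD, n = 3; log2 change -3.86 ± 0.45). PCK1, the rate-limiting enzyme of gluconeogenesis, fell from 2950 ± 503 to 173 ± 11.2 (-3.95 ± 0.42). S100A2, a calcium-binding protein of epithelial cells, rose in the same step by 5.41 ± 0.14 and the retinol dehydrogenase DHRS9 by 4.67 ± 0.40. Of 42 immediate early genes, 15 fell and 2 rose (16 and 2 adjusted over the list alone, camera adjusted p = 2.5e-07), a call lost with adjusted p = 0.071 with an estimated correlation. In the same step 17 of 42 cytoskeleton and adhesion genes rose (17 adjusted over the list alone, camera adjusted p = 3.1e-19), as did 14 of 29 ribosome biogenesis genes (14 adjusted over the list alone, camera adjusted p = 6.4e-17) and 7 of 9 metallothionein genes (7 adjusted over the list alone, camera adjusted p = 8.1e-09). Of 14 clock genes, 8 fell and 1 rose (9 and 2 adjusted over the list alone, camera adjusted p = 0.00039). The number of lower genes in this step was 274 with the larger pseudocount.

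Against 0 h, 757 genes were higher and 709 lower at 4 h. S100A2 went from 216 ± 10.3 to 24700 ± 3740 (SD, n = 3), a log2 change of 6.71 ± 0.14 (adjusted p = 1.1e-26). IL1RL1, the IL-33 receptor, rose by 6.79 ± 0.27, while its other probe set gave 1.02. MMP3, a matrix metalloprotease, rose by 5.58 ± 0.18, and KRT23, a keratin of the biliary marker list, by 5.46 ± 0.40. FOS fell by 4.02 on the log2 scale to 372 ± 83.3 and EGR1 by 2.49 to 1300 ± 154. CEBPA, a transcription factor that maintains hepatocyte differentiation, fell from 625 ± 35 to 60.3 ± 27.9 (-3.11 ± 0.35, adjusted p = 1.6e-08). CYP7A1, the rate-limiting enzyme of bile acid synthesis, fell from 470 ± 42.8 to 41.5 ± 32.9 (-3.18 ± 0.48). PIK3R1, the regulatory subunit of PI3-kinase, had a log2 change of -3.46 ± 0.17 (-2.43 and -2.17 by its other probe sets). The number of lower genes was 426 with the larger pseudocount and 589 without 0 h replicate 2, whose ACTB 3'/5' ratio stood apart.

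Of 24 NF-kappaB response genes, 14 rose at 4 h (14 adjusted over the list alone, camera adjusted p = 3.8e-12). They included F3, which encodes tissue factor (4.83 ± 0.23), TNFAIP3, a feedback inhibitor of NF-kappaB (3.64 ± 0.21), and the adhesion molecule ICAM1 (3.19 ± 0.21, and 3.16 and 1.02 by its other probe sets). Of 42 genes of the actin cytoskeleton, integrins and focal adhesions, 17 rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 4.1e-17), and of 29 ribosome biogenesis genes 15 rose (15 adjusted over the list alone, camera adjusted p = 2.1e-15). Of 9 genes on the metallothionein list, 7 rose (7 adjusted over the list alone, camera adjusted p = 2.5e-07), with MT1H at a log2 change of 2.19 ± 0.21 and MT1F at 2.02 ± 0.14. Metallothioneins bind zinc and copper and are near-identical paralogs, so single members are uncertain. Of 13 cholangiocyte markers, 6 rose (7 adjusted over the list alone, camera adjusted p = 0.00016). KRT19, a keratin of bile duct cells, went from 3360 ± 221 to 17500 ± 2760 (SD, n = 3). Of 29 mesenchymal genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 7.6e-05), and of 16 progenitor genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00087). CD44, a hyaluronan receptor on progenitor cells, rose from 816 ± 162 to 4940 ± 539. The Wnt antagonist DKK1 rose by 3.60 ± 0.17 and the Notch ligand JAG1, named from an _x_at probe set and uncertain, by 3.82 ± 0.21, while RNF43, a ubiquitin ligase that limits Wnt receptors, had a change of -2.56 ± 0.50. Among clock genes, CRY1 (1.93 ± 0.24) and PER2 (1.76 ± 0.25), both repressors of the circadian clock, rose at 4 h.

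Several liver function lists moved down as lists at 4 h, although few members were called. Cholesterol synthesis had 5 of 18 members lower (5 adjusted over the list alone, camera adjusted p = 2.5e-07), gluconeogenesis 4 of 12 (4 adjusted over the list alone, camera adjusted p = 0.0014) and plasma proteins 1 of 26 (1 adjusted over the list alone, camera adjusted p = 2e-04). Drug metabolism (4 of 30, camera adjusted p = 5.7e-05), bile acid and lipid metabolism (3 of 21, camera adjusted p = 0.0039) and fatty acid oxidation (2 of 19, camera adjusted p = 0.0016) were also called lower, with 4, 3 and 2 members adjusted over the list alone. These 3 calls were lost, with adjusted p = 0.053, 0.059 and 0.050 with an estimated correlation. The hepatocyte transcription factor list had 4 members lower and 1 higher of 17 (6 and 1 adjusted over the list alone, camera adjusted p = 0.042); its call was lost with adjusted p = 0.13 with an estimated correlation, and also without 0 h replicate 2. The amino acid and urea cycle list, with 2 members higher and 2 lower of 21 (2 and 2 adjusted over the list alone), was called lower with camera adjusted p = 0.0084, and this call was lost with adjusted p = 0.13 with an estimated correlation. The acute phase list was not called at 4 h (median -0.11, camera adjusted p = 0.20).

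At 8 h, cytoskeletal and adhesion genes were higher and drug-metabolizing enzymes lower than at 0 h. Against 0 h, 838 genes were higher and 1008 lower. AKAP12, a scaffold protein for protein kinase A, went from 611 ± 172 to 26200 ± 5260 (SD, n = 3; 5.39 ± 0.17, adjusted p = 7.7e-22), and RAC2, a small GTPase, from 178 ± 94.7 to 5160 ± 605. Of 42 cytoskeleton and adhesion genes, 24 rose (24 adjusted over the list alone, camera adjusted p = 1.7e-18), led by the tropomyosin TPM4 (4.37 ± 0.20), the collagen receptor subunit ITGA2 (3.20 ± 0.35) and the phospholipid-binding ANXA1 (3.05 ± 0.18). Of 29 ribosome biogenesis genes, 20 rose (20 adjusted over the list alone, camera adjusted p = 1.6e-16), including RRS1 (1.98 ± 0.16); NOP16 gave 2.38 ± 0.13, but 2.38, 0.36 and -0.93 by its other probe sets, and is uncertain. Of 16 progenitor genes, 7 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.0081). Those that rose included CD44 (2.96 ± 0.16, and 1.04 to 3.51 by its other probe sets), the TWEAK receptor TNFRSF12A (2.52 ± 0.15) and the intermediate filament gene NES (2.51 ± 0.29). HLF, a clock-controlled bZIP factor of liver, fell from 964 ± 92.4 to 17.4 ± 11.7 (-4.84 ± 0.43, other probe sets -2.13 and -4.46), and CYP4F3, a fatty acid hydroxylase, had a log2 change of -4.38 ± 0.24. Of 30 drug metabolism genes, 18 fell (18 adjusted over the list alone, camera adjusted p = 1.1e-11), and of 12 gluconeogenesis genes 8 fell (8 adjusted over the list alone, camera adjusted p = 5e-06).

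In the step from 4 to 8 h, 128 genes were higher and 193 lower, and early response lists came down. HLF (-3.36 ± 0.43, and -1.12 and -3.13 by its other probe sets) and IGFBP1, an insulin-repressed growth factor binding protein (-3.00 ± 0.33), had the largest falls. IGF2BP3, an oncofetal RNA-binding protein, rose by 2.37 ± 0.41 (1.32 and 0.99 by its other probe sets). Of 24 NF-kappaB response genes, 7 fell (7 adjusted over the list alone, camera adjusted p = 3.3e-05), and of 20 cytokines and chemokines 6 fell (6 adjusted over the list alone, camera adjusted p = 4.6e-05). With the larger pseudocount, 67 genes were higher and 124 lower in this step, and at 8 h against 0 h 654 were lower.

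From 8 to 12 h, DNA replication genes rose, and against 0 h liver enzymes and hepatocyte transcription factors were lower at 12 h. In the step from 8 to 12 h, 31 genes were higher and 17 lower, and 14 of 42 G1/S and replication genes rose (19 adjusted over the list alone, camera adjusted p = 8.1e-44). MCM10, a replication initiation factor, rose from 62.8 ± 13.1 to 321 ± 6.55 (SD, n = 3; 2.08 ± 0.31), and E2F1, a transcription factor of the G1/S transition, by 2.02 ± 0.38, while the other probe set of E2F1 gave 0.24. The number of lower genes in this step was 7 without 8 h replicate 3 and 10 without either 8 h replicate 1 or 12 h replicate 2; the number of higher genes was 20 with the larger pseudocount.

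Against 0 h, 869 genes were higher and 1052 lower at 12 h. G6PC1, the enzyme that releases glucose from glucose 6-phosphate, fell from 1180 ± 31.6 to 6.8 ± 5.58 (SD, n = 3; -5.61 ± 0.38, adjusted p = 1.6e-13). Of 12 gluconeogenesis genes, 9 fell (9 adjusted over the list alone, camera adjusted p = 3.5e-07), among them PPARGC1A, a coactivator of gluconeogenic genes (-2.29 ± 0.41). Of 17 hepatocyte transcription factors, 10 fell (10 adjusted over the list alone, camera adjusted p = 0.0011), and 9 did without 0 h replicate 2. They included CEBPA (-3.06 ± 0.35) and ONECUT1 (-3.49 ± 0.55), both regulators of hepatocyte differentiation, and PROX1 (-2.37 ± 0.53). Of 30 drug metabolism genes, 22 fell (22 adjusted over the list alone, camera adjusted p = 3.7e-16). Of 29 mesenchymal genes, 11 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.00021), led by MMP3 (5.21 ± 0.18), the matrix protein tenascin-C, TNC (4.74 ± 0.28, 1.55 by its other probe set), and thrombospondin, THBS1 (3.39 ± 0.20), whose other probe sets gave 1.54, 3.07 and -0.25. SNAI2 was still higher (1.30 ± 0.18), whereas SNAI1, VIM and CDH2, other genes of epithelial-mesenchymal transition, were not called at any time against 0 h. CDH1, which encodes E-cadherin, was called lower than at 0 h at every time from 8 h on. Its log2 change was -1.37 at 12 h and -1.31 at 24 h (-1.39 and -1.51 by its other probe set). At 8, 16 and 48 h it was -1, -1.67 and -1.17, where its other probe set gave -0.55, 0.01 and -0.77. The calls at 8, 16 and 48 h were lost with the mean of its probe sets. Of 17 heat shock genes, 7 rose (7 adjusted over the list alone, camera adjusted p = 1.8e-06), with the chaperone HSPB1 at 1.96 ± 0.16 and the co-chaperone CHORDC1 at 2.09 ± 0.18.

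Few genes separated 16 h from 12 h. In that step, 11 genes were higher and 13 lower. E2F8, an E2F factor of S phase, rose by 1.69 ± 0.29 and PCLAF, which binds PCNA, by 1.46 ± 0.14, while CYP1A1, an aryl hydrocarbon receptor target, fell from 1310 ± 60.6 to 291 ± 138 (SD, n = 3). These counts rest on single arrays: without 12 h replicate 3, 7 genes were higher and 2 lower, without 12 h replicate 1, 8 were lower, and without 16 h replicate 1, 21 were lower. Fitted without a mean-variance trend, 7 were lower.

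Against 0 h, 916 genes were higher and 1188 lower at 16 h. GLIPR1, a p53-regulated gene, rose from 285 ± 71.2 to 10200 ± 91.8 (SD, n = 3; 5.11 ± 0.15, adjusted p = 4.3e-23, other probe sets 2.45 and 3.28) and ANXA3, an annexin, by 4.69 ± 0.23. Of 26 YAP and SRF targets, 12 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 1.8e-06), with TGFB2, a TGF-beta ligand, at 4.59 ± 0.32 (1.91, 0.10 and 1.38 by its other probe sets), and FHL2, a LIM-domain cofactor, at 3.19 ± 0.16. EREG, an EGF receptor ligand, rose by 4.22 ± 0.36, while the growth hormone receptor GHR (-2.26 ± 0.19) and the receptor tyrosine kinase ERBB3 (-2.14 ± 0.24, other probe set -1.19) fell. Of 19 fatty acid oxidation genes, 11 fell (11 adjusted over the list alone, camera adjusted p = 1.2e-08), including ACSL1 (-3.01 ± 0.17), EHHADH (-2.71 ± 0.22) and CPT2 (-1.39 ± 0.25), which activate, degrade and import fatty acids. Of 21 genes of IL-6 family receptors and JAK-STAT signalling, 8 fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.032), a call lost with adjusted p = 0.061 with an estimated correlation; the receptor IL11RA was lower (-2.64 ± 0.52) and the feedback inhibitor SOCS2 higher (1.73 ± 0.17). RDH16, a retinol dehydrogenase of liver, fell from 783 ± 242 to 5.81 ± 0.718.

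By 24 h, mitotic genes had risen and most liver enzymes had fallen. In the step from 16 to 24 h, 82 genes were higher and 49 lower, and 29 of 40 G2/M genes rose (33 adjusted over the list alone, camera adjusted p = 1.5e-56). MXD3, of the MYC network, rose by 2.55 ± 0.50 and HJURP, the chaperone of centromeric histone, by 2.39 ± 0.43. FABP1, the fatty acid binding protein of liver, fell from 4600 ± 1190 to 831 ± 34.6 (SD, n = 3; -2.41 ± 0.20). Against 0 h, 37 of 40 G2/M genes rose (37 adjusted over the list alone, camera adjusted p = 1.1e-23) and 32 of 42 G1/S genes (33 adjusted over the list alone, camera adjusted p = 8.3e-17). CDK1, the kinase that drives entry into mitosis, went from 554 ± 136 to 5030 ± 613 (SD, n = 3; 3.16 ± 0.21, adjusted p = 4.2e-14) and GINS1, part of the replicative helicase, from 360 ± 49.3 to 2440 ± 61.6. Without 0 h replicate 2, 36 G2/M and 32 G1/S genes rose.

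Against 0 h, 1039 genes were higher and 1119 lower at 24 h. Of 30 drug metabolism genes, 27 fell (27 adjusted over the list alone, camera adjusted p = 9.6e-26), with a list median of -2.80; the sulfotransferase SULT2A1 went from 6450 ± 555 to 140 ± 81.4 and the alcohol dehydrogenase ADH1B from 14900 ± 1290 to 470 ± 247 (SD, n = 3). Of 21 amino acid and urea cycle genes, 17 fell (18 adjusted over the list alone, camera adjusted p = 1.4e-15), including ARG1 (-5.69 ± 0.27) and CPS1 (-3.95 ± 0.26), the last and first enzymes of the urea cycle. Of 21 bile acid and lipid genes, 18 fell (18 adjusted over the list alone, camera adjusted p = 6e-13), with FABP1 at -4.83 ± 0.20 and MTTP, needed for lipoprotein assembly, at -3.35 ± 0.22. Of 18 cholesterol synthesis genes, 15 fell (15 adjusted over the list alone, camera adjusted p = 9e-14), led by SC5D (-3.00 ± 0.15) and TM7SF2 (-2.86 ± 0.17), which are enzymes, and INSIG1 (-2.73 ± 0.18), a sterol sensor. Of 18 glucocorticoid response genes, 11 fell and 2 rose (11 and 2 adjusted over the list alone, camera adjusted p = 0.00038), with the tyrosine aminotransferase TAT (an uncertain _x_at probe set) at -2.77 ± 0.40 and the lipase inhibitor ANGPTL4 at 2.27 ± 0.19. Without 0 h replicate 2, 26 drug metabolism, 17 amino acid, 16 bile acid and lipid and 15 cholesterol synthesis genes fell.

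At 48 h all 26 measured plasma protein genes were lower than at 0 h (26 adjusted over the list alone; 25 without 0 h replicate 2), with a list median of -2.40 and camera adjusted p = 9.6e-28. APOB, the core protein of low-density lipoprotein, fell from 26100 ± 4970 to 999 ± 259 (SD, n = 3; -4.70 ± 0.19, adjusted p = 1.9e-19), and the kininogen KNG1 and coagulation factor F9 had log2 changes of -3.96 ± 0.16 and -3.76 ± 0.18. ALB, which encodes albumin, had 69400 ± 9270 at 0 h and 33000 ± 1100 at 48 h, a change of -1.07 ± 0.14 that dropped under 2-fold with quantile normalization (-0.65), with median centring (-0.92) and without 0 h replicate 2 (-0.98). The other 2 probe sets of ALB gave -3.56 and 0.01, so the size of its fall is uncertain. Of 16 acute phase genes, 14 fell (14 adjusted over the list alone, camera adjusted p = 6.4e-15), including the inter-alpha-trypsin inhibitor chain ITIH4 (-3.84 ± 0.18), the complement inhibitor SERPING1 (-3.09 ± 0.15) and complement C3 (-2.69 ± 0.12). Of 30 drug metabolism genes, 27 fell (27 adjusted over the list alone, camera adjusted p = 3.7e-29). CYP2E1, an ethanol-inducible cytochrome P450, fell from 9350 ± 604 to 45.5 ± 42.5 (-7.43 ± 0.24, adjusted p = 8.7e-22). CYP3A4, the main drug-oxidizing P450, had -7.23 ± 0.20 from an _x_at probe set, and -1.28, not called, when such probe sets were left out, so its value is uncertain. In total 979 genes were higher and 1170 lower at 48 h. Across the 7 hepatocyte lists, from plasma proteins to gluconeogenesis, 117 of 143 measured members fell, and 117 did without 0 h replicate 2.

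**Figure D3:**
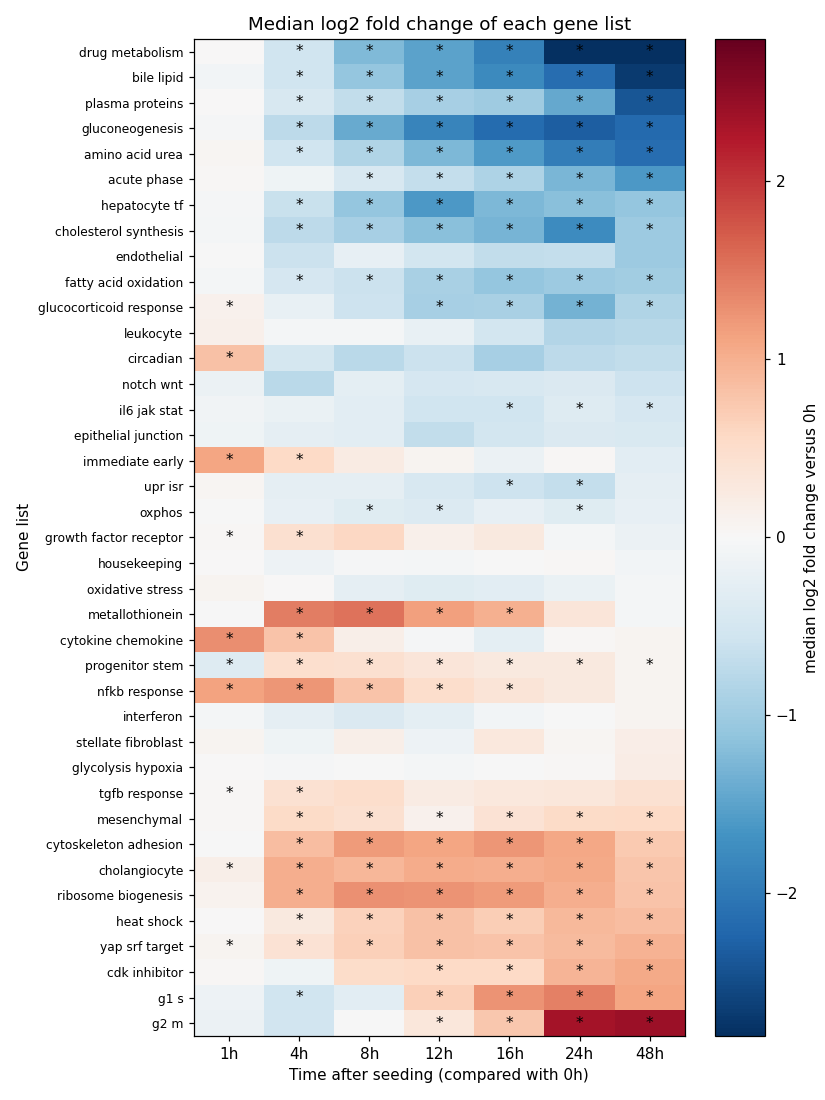
The heatmap gives, for each of 39 gene lists (lines) at each of 7 times (columns, hours), the median log2 change of the list's measured genes against 0 h, with a star where camera's adjusted p was under 0.05. Drug metabolism reached -2.80 at 24 h and plasma proteins -2.40 at 48 h, while the G2/M list reached 2.39 at 48 h.

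The G1/S and G2/M lists were higher at 48 h than at 0 h. Among single genes, S100A2 stood at 46900 ± 4980 (SD, n = 3; 7.64 ± 0.14, adjusted p = 1.9e-28), LGALS1, a galactose-binding lectin, at 13700 ± 1300 against 175 ± 52.5, and POSTN, a matrix protein, at 3800 ± 506 against 176 ± 44.2. AGR2, a protein disulfide isomerase of secretory epithelia, went from 7.4 ± 2.29 to 1850 ± 554. Of 40 G2/M genes, 39 rose (39 adjusted over the list alone, camera adjusted p = 1.2e-26, and 36 without 0 h replicate 2). Among them were the cyclin CCNB1, from 151 ± 15.9 to 4500 ± 93.1, and the mitotic activator CDC20 (3.96 ± 0.20). The survivin gene BIRC5 rose by 3.46 ± 0.24 (2.69 and 2.17 by its other probe sets). Of 42 G1/S genes, 25 rose (25 adjusted over the list alone, camera adjusted p = 4.2e-12). Of 16 CDK inhibitors and p53 targets, 8 rose (9 adjusted over the list alone, camera adjusted p = 5.4e-05). Of these, CDKN3 (1.94 ± 0.19) encodes a phosphatase of CDK proteins whose expression peaks in dividing cells, and PLK2 (1.94 ± 0.20) a stress-responsive kinase. CDKN1A, the p21 gene on that list, had a change of 0.20 ± 0.13 at 12 h and was not called at any time against 0 h. Of 26 YAP and SRF targets, 12 rose (12 adjusted over the list alone, camera adjusted p = 8.4e-07). KRT19 was higher (2.25 ± 0.15) and CEBPA lower (-2.39 ± 0.35). Among TGF-beta response genes, for which camera gave adjusted p = 0.28 with 8 higher and 5 lower of 26 (8 and 5 adjusted over the list alone), TGFB2 (4.22 ± 0.32, and 1.35, 0.17 and 1.01 by its other probe sets) and the transcriptional inhibitor ID3 (2.26 ± 0.17) rose and the activin subunit INHBE fell (-2.62 ± 0.33).

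From 24 to 48 h, 32 genes were higher and 87 lower, and plasma proteins fell further, with 9 of 26 members lower (9 adjusted over the list alone, camera adjusted p = 2.5e-40). CYP2E1 changed by -3.53 ± 0.24 in this step (-2.10 and -2.39 by its other probe sets) and AGR2 rose by 2.33 ± 0.50, a call lost without a pseudocount (adjusted p = 0.12). The number of higher genes was 52 without 24 h replicate 3. The comparison of 48 h with 1 h tested whether the early response lists had come down again, and 1079 genes were higher and 1147 lower. The list counts cover all measured members, also those that had not risen at 1 h. Of 42 immediate early genes, 28 fell from 1 to 48 h (28 adjusted over the list alone, camera adjusted p = 2.2e-19), as did 11 of 20 cytokines and chemokines, where 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 1.4e-05), and 8 of 14 clock genes (8 adjusted over the list alone, camera adjusted p = 7.1e-05). CCL2 at 998 ± 73.2 (SD, n = 3) was still above its level at 0 h (3.78 ± 0.21). Against 0 h, 11 immediate early genes were lower at 48 h and 7 higher (11 and 7 adjusted over the list alone), camera did not call the list (adjusted p = 0.089), and without 0 h replicate 2, whose ACTB 3'/5' ratio was 6.91, 10 were lower and 6 higher. FOS fell to 27.5 ± 26.4 (-7.27 ± 0.43, adjusted p = 2.5e-15) and EGR1 to 809 ± 141 (-3.18 ± 0.21).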

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

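Apart from leaving out each replicate for the gene lists, all alternatives were chosen before the data were examined. Of 388 values of named genes, 369 kept their call and direction with the larger pseudocount, 369 with quantile normalization, 366 with median centring, 375 without a pseudocount, and 384 each without the filter, without a mean-variance trend and with only the groups compared. With the mean of a gene's probe sets, 14 became weaker, 10 stronger and 13 turned direction. All 321 values that the stricter filter left were kept, and 374 of 386 without _x_at probe sets. With each array left out in turn, 2161 of 2328 values were kept and 58 turned direction. The F-test called 5414 to 6046 genes under the alternatives and 5657 to 5846 with 1 array left out, against 5870. Among results called under no setting, 48 h against 0 h not counted (79 for genes, 156 for lists), 24 of 851 gene values and 46 of 624 list values turned direction, and with 1 array left out 45 of 474 and 105 of 936.

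With the larger pseudocount, lower genes went from 60 to 25 at 1 h, from 709 to 426 at 4 h and from 1008 to 654 at 8 h, and in the steps from 443 to 274 lower (1 to 4 h), from 128 to 67 higher and 193 to 124 lower (4 to 8 h) and from 31 to 20 higher (8 to 12 h). Lower genes at 1 h numbered 39 with the stricter filter and 22 with only the groups compared, and lower genes from 12 to 16 h numbered 7 without a mean-variance trend, against 13. Leaving out 1 array gave 7 to 14 lower genes from 8 to 12 h, 2 to 21 lower and 7 to 16 higher from 12 to 16 h, and 25 to 52 higher from 24 to 48 h.

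Some gene changes turned direction. ALB at 1 h was -0.01, and 0.07 with median centring, while its other probe sets gave -3.14 and -1.36, so its change at 1 h is uncertain. CXCL8 was -0.45 at 12 h and -0.41 at 16 h, and 0.27 and 0.08 with the mean of its probe sets; without _x_at probe sets it was 0.99 at 12 h, 0.57 at 16 h, 0.05 at 24 h (-0.32 in the main analysis) and 0.29 at 48 h (-1.13). CYP3A4 at 16 h was -1.65, and 0.07 without _x_at probe sets. With 1 array left out, SOCS3 at 4 h ranged from -0.57 to 0.19, IL6 at 48 h from -0.1 to 0.15, MYC at 48 h from -0.62 to 0.02, ALB at 1 h from -0.12 to 0.09, and CXCL8 from -0.47 to 0.78 at 8 h, -1.2 to 0.04 at 12 h, -1.16 to 0.08 at 16 h and -1.07 to 0.18 at 24 h.

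Of 546 list tests, 479 kept their result with an estimated correlation and the other 67 lost the call; 395 kept it with fry and 518 with quantile normalization, and no called list turned direction. With 1 array left out, 3067 of 3276 list tests were kept and 111, none of them called, turned direction. Among lists not called, the gene list notch_wnt 48h versus 0h had adjusted p = 0.907 and 0.149 with fry. With 1 array left out, adjusted p ranged from 0.0351 to 0.891 for gene list immediate_early 16h versus 0h (0.398 with all arrays), from 0.845 to 0.974 for notch_wnt and from 0.583 to 0.974 for gene list metallothionein 48h versus 0h (0.986).

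The replicate number as a block left 387 of 388 gene values and 544 of 546 list tests as they were, with 5835 genes past the F-test, 55 lower genes at 1 h, and 979 higher and 1167 lower genes at 48 h. Arrays sharing a number at different times did not deviate together (mean correlation 0.001, -0.067 to 0.065 over 84 pairs of arrays), and 12 of 24 arrays correlated best with their own number.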

Other observations

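The lists, the interferon and clock genes among them, were fixed before the data were examined; HMGCS1, INSIG1 and HSPA5 in the last step were chosen after their values were seen, as were all splits of the arrays and the tests of the share of hepatocyte-like cells and of the course of cholangiocyte markers. From 24 to 48 h, genes of cholesterol synthesis and of the unfolded protein response moved up as lists. Against 0 h, the first list had been called lower from 4 to 24 h and the second at 16 and 24 h. Of 18 cholesterol synthesis genes, 2 rose in this step (2 adjusted over the list alone), with a list median of 0.62 and camera adjusted p = 3.4e-15. The HMG-CoA synthase HMGCS1 had a log2 change of 1.20 ± 0.15 and the sterol sensor INSIG1 1.53 ± 0.18. Of 29 unfolded protein response genes, 1 rose (1 higher and 1 lower adjusted over the list alone, median 0.29, camera adjusted p = 2.3e-08), and the chaperone HSPA5 had a log2 change of 0.92 ± 0.16 (adjusted p = 0.00031), under the 2-fold limit. At 24 h, 7 genes of this list had been lower and 2 higher than at 0 h (7 and 2 adjusted over the list alone, camera adjusted p = 0.00076), among them DNAJB9, a chaperone of the endoplasmic reticulum (-1.91 ± 0.14), and SEL1L, needed for protein disposal from it (-1.72 ± 0.15, other probe sets -0.82, -0.90 and -0.74). G1/S genes as a list were lower at 48 h than at 24 h (median -0.32, camera adjusted p = 4.8e-07).

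Clock and hypoxia genes moved in both directions. PER2 and CRY1 rose at 4 h by 1.76 ± 0.25 and 1.93 ± 0.24 while HLF fell at 8 h to 17.4 ± 11.7 (SD, n = 3), and at 48 h the clock list had 5 members lower and 1 higher of 14 (6 and 1 adjusted over the list alone, camera adjusted p = 0.12). Of 24 glycolysis and hypoxia genes, 4 rose and 4 fell at 48 h (4 and 4 adjusted over the list alone, camera adjusted p = 0.49): PFKP, a phosphofructokinase, went from 137 ± 46.1 to 1390 ± 256 and the oxygen sensor EGLN3 from 68.6 ± 53.4 to 793 ± 71.1, while VEGFA, a hypoxia-induced angiogenic factor, fell from 1140 ± 49.2 to 207 ± 72.8 (SD, n = 3), a log2 change of -2.42 (-0.80, -1.45 and -1.22 by its other probe sets). Of 26 interferon-stimulated genes, 5 rose and 1 fell at 48 h (5 and 1 adjusted over the list alone, camera adjusted p = 0.14); at 24 h the exonuclease ISG20 was higher (2.24 ± 0.32) and IFIT2 lower (-2.28 ± 0.49). Of 17 epithelial junction genes, 2 rose and 3 fell at 48 h (2 and 3 adjusted over the list alone, camera adjusted p = 0.35); at 16 h the tight junction gene CLDN14 (-3.31 ± 0.56) and the connexin GJB1 (-1.66 ± 0.24) were lower. Of 23 oxidative stress genes, 1 rose and 3 fell at 48 h (1 and 3 adjusted over the list alone, camera adjusted p = 0.70); at 12 h GCLC, an enzyme of glutathione synthesis, was lower (-1.83 ± 0.14). Of 17 Notch and Wnt genes, 3 rose at 48 h (3 adjusted over the list alone, camera adjusted p = 0.91), with a median of -0.57 and a mean of 0.02. Of 27 oxidative phosphorylation genes, 1 fell at 24 h (1 adjusted over the list alone, camera adjusted p = 0.008), a call lost with adjusted p = 0.15 with an estimated correlation.

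Markers of other cell types were not called as lists against 0 h. At 48 h camera gave adjusted p = 0.21 for stellate cell and fibroblast genes (3 higher and 1 lower of 12), 0.18 for endothelial genes (3 lower of 10) and 0.27 for leukocyte genes (1 higher and 2 lower of 14), and adjusted over the list alone the counts were 3 and 1, 2 lower, and 1 and 2. LUM, a matrix proteoglycan, was higher at 48 h (2.08 ± 0.26) and the endothelial receptor KDR lower (-2.15 ± 0.59). Of 13 genes often used as references, 2 rose and 1 fell at 48 h (2 and 1 adjusted over the list alone, camera adjusted p = 0.46); at 24 h YWHAZ rose by 1.77 ± 0.14 and HPRT1 by 1.34 ± 0.13.

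The fall of hepatocyte genes at 48 h, 117 of 143 list members, was weighed against scaling, 0 h replicate 2 and a lower share of hepatocyte-like cells. The counts argue against the first 2, because 112 members were lower under the less favourable of the 2 other scalings and 117 without that array (both bounds were set before). A lower share alone could lower members unequally but would move them in step. Of 62 members of middle signal called lower at 48 h, 20 (32.3%, and 30.6% with quantile normalization) had reached by 8 h a part of their fall apart from the median part of 64.6%. This is past the bound for this test and argues against share alone as the cause of the whole fall. That bound, like those of the 2 other tests of share below, was set after the fall was seen. In 2 other tests, 13 of 70 members of middle signal (18.6%) were reliably above a 2-fold fall at 8 h while 41 were called lower, and from 24 to 48 h 4 (3 with quantile normalization) lost more signal than the share left at 24 h would allow, both short of their bounds. A lower share as part of the cause stays open, and RNA from sorted cells or counts of hepatocyte-like cells at each time would test it.

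The rise of cholangiocyte markers at 4 h, with 6 of 13 called, was weighed against a larger share of biliary-like cells, which might raise all of them together. From 4 to 48 h KRT23 (-5.18 ± 0.40) and SOX9 (-1.42 ± 0.17) were called lower, while KRT19 (-0.12 ± 0.15), SPP1 (-0.16 ± 0.20), KRT7 (-0.27 ± 0.40) and DEFB1 (-0.61 ± 0.17) were not called; the smaller of the counts moving up and down, 0, did not reach the bound set before. A further test and its bound were set after the values were seen. A change of share alone would move the members in step. In 2 of the 6, KRT23 and SOX9, the part of the rise left at 48 h lay apart from the median part of 60% under all 3 scalings. This only just met the bound of 2. The rise of SOX9 at 4 h was not firm, as given below, so the test does not decide whether share alone explains the course from 4 to 48 h. Before 4 h, SOX9 was out of step: its log2 change against 0 h was 2.31 at 1 h and 1.01 at 4 h. Its other probe set gave 2.53 and 0.46. KRT19 had signals of 4062 to 5023 at 1 h and 14690 to 20200 at 4 h, and KRT23 and DEFB1 were also higher at 4 h than at 1 h. Of these, SOX9 alone went the other way. On this single member, a larger share and higher expression cannot be told apart for the rise at 4 h itself. The rise of SOX9, one of the 6, 1.01 ± 0.17, was under 2-fold without 0 h replicate 3 (0.88), 0 h replicate 1 (0.97) or 4 h replicate 1 (0.97), with the mean of its probe sets (0.73) and with the larger pseudocount (0.93), its other probe set gave 0.46, and KRT7 was also under 2-fold with the larger pseudocount (0.93), so the count of 6 is not firm.

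The high level of immediate early genes at 0 h was weighed against the single array 0 h replicate 2. Without that array, 10 of the 11 members lower at 48 h were again called lower, past a bound set before, which argues against it as the cause. Handling of the cells before 0 h could also raise these genes, and with no sample from undisturbed cultures among the 24 this was not tested here; the 10 members above do not bear on it.

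Each comparison was repeated over all 10 ways to split its 6 arrays into 3 and 3, a test chosen after the result was seen. The true grouping gave the highest count each time, 1 of 10 splits, which is too few for a share under 0.05. Against 0 h the true count and the highest other count were 281 and 4 at 1 h, 1466 and 2 at 4 h, 1846 and 2 at 8 h, 1921 and 0 at 12 h, 2104 and 1 at 16 h, 2158 and 1 at 24 h, and 2149 and 1 at 48 h. For the steps they were 1089 and 2, 321 and 2, 48 and 1, 24 and 1, 131 and 3, and 119 and 5 in order of time, and 2226 and 0 for 48 h against 1 h. In 100 groupings of the 24 arrays, the true one included, the F-test called 5870 genes for the true one and at most 420 for any other, so 1 of 100 reached the true count.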
